A study of Homo sapiens with 2 samples.

How the data were processed

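The series holds 2 single-cell RNA-seq libraries made from the head and neck squamous cell carcinoma of 1 patient. Per the labels' protocols, the tumour was diced and run 5 times on a tissue dissociator in 1 ml of medium, which gave the mechanical library. The solid tissue left in the strainer then received 4 ml of medium and 0.5 ml of a collagenase (3000 U/ml) and hyaluronidase (1000 U/ml) mix, which gave the enzymatic library. Live cells were sorted by FACS before droplet-based 3' library preparation with the version 3 kit of 10x Genomics, per the labels' protocols. The length and temperature of the enzyme step are not given in the sources used here.

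The authors deposited raw UMI counts per gene and barcode, as filtered matrices of barcodes called as cells, with no normalization. The counts were made with Cell Ranger, version 3.1.0 per the file headers and version 3.3 per the submitters' processing notes, on GRCh38.p14 per the same notes. Both matrices list the same 33538 genes, paired with Ensembl identifiers. Symbols with 2 identifiers were read from the first one (RGS5 and SOD2 among the listed genes). Gene positions come from GENCODE release 29 on GRCh38. Reads were not used here, so barcodes below the submitters' cell call, and with them a direct measure of free RNA, were not analysed here.

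Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept. Scrublet, run within scanpy 1.11.5 on each library with expected rates of 2% (enzymatic) and 1% (mechanical), called 1 and 2 doublets, 0.116% of the filtered barcodes. That is too few to count as doublet removal, so doublets remain in all values. Both libraries were clustered together: counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components were used with 15 neighbours, and Leiden (igraph 0.11.9) at resolution 1 gave 21 clusters. No correction between libraries was made. Clusters were named by 17 marker lists. The name was that of the list with the highest mean log2 ratio of CPM to all other cells (10 CPM added), given at least 3 markers with a UMI in 10% of the cluster's cells and a mean of at least 0.5. A cluster with more markers of another class among its top 10 genes by ratio (genes with a UMI in 25% of its cells) stayed unnamed. T and NK clusters were joined as T or NK-like.

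For classes with at least 50 kept cells in each library, and for all kept cells together, UMIs were summed per library and scaled to CPM. The log2 ratio of enzymatic to mechanical CPM has a prior of 1 count. CPM intervals are exact 95% Poisson intervals, fold intervals are exact 95% conditional binomial intervals, and shares of cells have exact 95% Clopper-Pearson intervals. The interval of a difference in shares was combined from both exact intervals by Newcombe's method. With 1 library per step no test was made, and all intervals cover counting error only. A count of 0 was bounded by 3 counts in that library. A gene is called higher or lower only where its fold is at least 1.5 and the Poisson intervals of both sums do not overlap. Counts of higher and lower genes after centring on the median gene use the fold of 1.5 alone, without the interval rule. Each of the 23 gene lists is summarised by the median log2 ratio of members with at least 20 UMIs. Beside it stands the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs. Thinning left out 16 enzymatic and 3 mechanical monocyte or macrophage-like cells, and 15 and 7 T or NK-like cells.

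Genes were named by a fixed rule. It takes the 8 highest and 8 lowest log2 ratios per class among genes with at least 50 UMIs and a UMI in at least 10% of the class's cells in a library. Their CPM also had to reach 0.5 times that of all other cells in the library where they were higher. Immunoglobulin and T cell receptor genes, mitochondrial, ribosomal and sex-linked marker genes and clone-named genes were left out of the ranking. Members of the gene lists and markers could also be named. Not every gene that the rule took is reported here.

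The filters, the clustering settings, the gene lists, the markers, the naming rule for genes and most alternatives were chosen before the data were examined. The score that names clusters and its limits, the joining of T with NK and of monocytes with dendritic cells, the Scrublet rates and the panel of free RNA genes were set afterwards. Alternatives covered the mitochondrial limit, the cell filter, doublets, Leiden resolutions of 0.5 and 2, separate clustering, clustering without stress genes, scoring of each cell, unnamed clusters counted under their best match (added afterwards), the CPM scaling, the prior, the UMI minimum of list members and the thinning depth.

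The gene statistics were tested on simulated data with 200 genes changed by known folds, as a check of counting error alone. Variation between cells, clusters or libraries was not part of this check. The shares below therefore do not give the rate of false calls between the real libraries. The simulations held fewer genes than the real T or NK-like (10386) and monocyte or macrophage-like (9546) comparisons, so they do not cover every gene called here. In the simulated T or NK comparison, with 8355 genes, the size rule found 90.0% of genes raised 2-fold and 78.0% of genes set to 0.5 of their level, and 99.7% of unchanged genes were left uncalled. In the simulated monocyte or macrophage comparison, with 7277 genes, these shares were 86.0%, 74.0% and 99.6%.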

Results

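Cells from 1 head and neck squamous cell carcinoma, a tumour of the squamous lining of the mouth and throat, were profiled in 2 droplet-based single-cell RNA-seq libraries. The mechanical library holds cells freed by the tissue dissociator. The enzymatic library holds cells freed afterwards from the solid residue by collagenase and hyaluronidase, which cut collagen and hyaluronan of the extracellular matrix. The series compares these dissociation methods, so the question is which cells and which transcripts each step yields. Step and tissue fraction go together, and there is 1 library per step, so no difference has a replicate check. The enzymatic library held 15167455 UMIs in 2643 barcodes (median 3419 per barcode), and the mechanical library 6666077 UMIs in 1344 barcodes (median 3199). Barcodes with more than 20% mitochondrial UMIs made up 33.4% (95% exact binomial interval 31.6 to 35.2) of the enzymatic and 38.1% (35.5 to 40.8) of the mechanical library. The filter left 1758 enzymatic and 827 mechanical cells, with medians of 4287.5 and 4313 UMIs.

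Fibroblast-like and epithelial-like cells made up larger shares of the enzymatic library, and leukocytes a larger share of the mechanical library. Fibroblast-like cells, the collagen-producing cells of connective tissue, were 11.3% of enzymatic cells (198 cells, interval 9.82 to 12.8) and 0.605% of mechanical cells (5 cells, 0.197 to 1.41), an 18.6-fold difference in share. Epithelial-like cells, which express keratins, were 7.45% (131 cells, 6.27 to 8.78) against 1.21% (10 cells, 0.581 to 2.21). Of these, 96 enzymatic and 5 mechanical cells had under 2% mitochondrial UMIs and a MALAT1 median of 0. The others were 1.99% (1.39 to 2.76) of enzymatic and 0.605% (0.197 to 1.41) of mechanical cells. These intervals overlapped only from 1.39 to 1.41, which does not make the shares alike. No interval of their difference was taken. The limit of 2% was set after the data were seen. Plasma-like cells, which secrete antibodies, were 4.04% (71 cells, 3.17 to 5.07) against 0.846% (7 cells, 0.341 to 1.74). Pericyte or smooth muscle-like cells were 0.967% (17 cells) of the enzymatic library, and 0 of 827 mechanical cells allows a share of up to 0.363% by the floor of 3 counts. With each cell scored on its own, 35 enzymatic (1.99%) and 11 mechanical cells (1.33%) had that name, and the difference of 0.661 points (-0.538 to 1.68) was not detectable. That scoring also gave names of classes with no cluster, such as skeletal muscle (14 enzymatic and 10 mechanical cells) and Schwann (20 and 6). T or NK-like cells fell to 715 and 442 under it, so its names in rare classes are less certain.

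Leukocyte classes together were 93.8% (92.0 to 95.4) of mechanical and 79.8% (77.9 to 81.7) of enzymatic cells. T or NK-like lymphocytes were 60.7% (502 cells, 57.3 to 64.0) of the mechanical and 48.1% (845 cells, 45.7 to 50.4) of the enzymatic library. Neutrophil-like cells, short-lived phagocytes with little RNA, were 4.23% (35 cells, 2.97 to 5.84) of mechanical and 0.284% (5 cells, 0.0924 to 0.662) of enzymatic cells, a ratio of 14.9. With each cell scored on its own these shares were 4.84% (3.48 to 6.53) and 1.42% (25 cells, 0.922 to 2.09), a ratio of 3.40. The median of the clustered neutrophil-like cells in the mechanical library was 727 UMIs, near the lowest count of 500 UMIs in any deposited barcode. Endothelial-like cells, led by the lymphatic genes CCL21 and MMRN1, were 1.93% (16 cells, 1.11 to 3.12) of mechanical and 0.398% (7 cells, 0.160 to 0.819) of enzymatic cells. Monocyte or macrophage-like cells were 17.4% (306 cells, 15.7 to 19.3) of enzymatic and 21.0% (174 cells, 18.3 to 24.0) of mechanical cells, with overlapping intervals and a difference of -3.63 points (-7.05 to -0.332). With at most 10% mitochondrial UMIs this difference was -11.8 points. The intervals also overlapped for B-like (4.89% and 3.39%), mast-like (2.96% and 1.69%) and dendritic-like cells (2.16% and 1.93%). They did not for mast-like cells without a cell filter (3.52%, 2.85 to 4.29, against 1.42%, 0.854 to 2.20), nor for dendritic-like cells clustered without stress genes (12.1%, 10.6 to 13.7, against 7.62%, 5.90 to 9.64). In that last setting monocyte or macrophage-like cells fell to 133 and 147. Joined with dendritic-like cells they were 345 and 210, against 344 and 190 as reported, so the dendritic gain came with a change of names. With each library clustered on its own, dendritic-like cells were 2.90% (2.17 to 3.80) against 6.89% (5.26 to 8.84). B-like cells were then 4.89% against 0%, and neither pair of intervals overlapped. An unnamed cluster, with OLIG2 and the hypoxia-responsive genes HILPDA, HK2 and VEGFA among its leading genes, held 0.114% of enzymatic and 2.42% of mechanical cells. All shares follow the sort for live cells and the mitochondrial filter. With each library clustered on its own, the difference turned for monocyte or macrophage-like cells (9.99 points, enzymatic minus mechanical), plasma-like cells (-0.193 points), dendritic-like cells (from 0.227 to -3.99 points) and monocyte, macrophage or dendritic-like cells together (from -3.41 to 5.996 points). For all leukocytes it was then -2.97 points (-6.14 to 0.331), against -14.0 in the joint clustering. The mechanical library then had 94 cells in an unnamed cluster led by EREG and MCEMP1, and 35 plasma-like cells with no B-like cluster. That unnamed cluster matched the monocyte or macrophage markers best. Counted in that class, a step chosen after the data were seen, it left a difference of -1.38 points (-4.69 to 1.80) for monocyte or macrophage-like cells, -5.37 with dendritic-like cells joined and -14.3 for all leukocytes, so these did not turn. With at most 10% mitochondrial UMIs the differences kept their direction and were larger for epithelial-like (12.7 points), plasma-like (6.81), neutrophil-like (-9.33) and all leukocyte cells (-25.3). Without a cell filter those of T or NK-like and endothelial-like cells were -7.88 and -3.49 points, against -12.6 and -1.54.

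**Figure D1:**
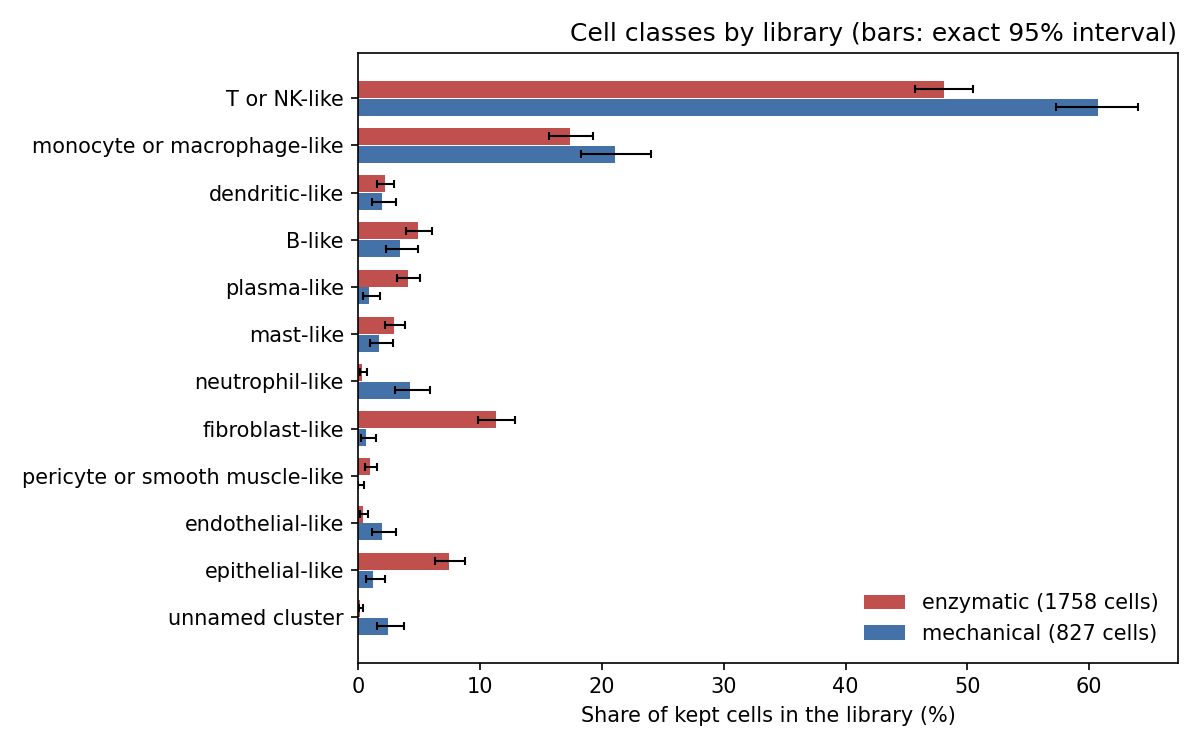
Share of kept cells per class in the enzymatic (1758 cells) and mechanical (827 cells) library, in percent, with exact 95% binomial intervals as error bars. Fibroblast-like cells stand at 11.3% and 0.605%, and neutrophil-like cells at 0.284% and 4.23%.

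Summed over all kept cells, genes of connective tissue matrix were higher in the enzymatic library. ASPN and LUM, which encode small leucine-rich proteoglycans of collagen fibrils, were 77.2-fold (49.4 to 128) and 65.7-fold (56.4 to 76.9) higher in the enzymatic library. DIO2, which encodes a thyroid hormone deiodinase, and THBS2 followed with 51.8-fold and 48.9-fold, then COL1A2 (42.9-fold), DCN (41.5-fold), COL1A1 (40.3-fold) and COL6A3 (40.3-fold). COL1A1, on chromosome 17 from 50183289 to 50201632, stood at 2514 CPM in the enzymatic and 62.4 CPM in the mechanical library. All 12 matrix fibroblast genes were higher, with a median log2 ratio of 4.51. Of 9 measured inflammatory fibroblast genes 7 were higher, among them the chemokine genes CXCL14 (11.7-fold) and CXCL12 (8.16-fold) and the receptor gene PDGFRA (14.2-fold). IGF1 (17.1 and 18.0 CPM) and CFD (31.8 and 43.3 CPM) were not called.

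Keratinocyte genes were also higher in the enzymatic sum. Of 14 measured squamous differentiation genes 10 were higher, such as IVL, which encodes a protein of the cornified envelope (18.6-fold, 7.13 to 69.0), and KRT6B (10.6-fold). Of 9 basal keratinocyte genes 6 were higher, including KRT14 (7.94-fold) and KRT5 (3.33-fold), and 3, including KRT15, were not called. In the partial EMT list, named for tumour cells with mesenchymal traits, 7 of 11 genes were higher, led by the collagenase gene MMP1 (17.7-fold) and PTHLH (9.23-fold), while TGFBI was lower (1 gene, and 0 after centring on the median gene). MMP1 is also a fibroblast gene. HBB, which encodes beta globin, had 254 UMIs in 0.114% of the enzymatic cells and 0 UMIs in the mechanical cells.

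Among the lowest ratios over all cells was that of CISH. This gene, a feedback inhibitor of cytokine signalling, was 6.11-fold lower in the enzymatic library (4.60 to 8.18), and the macrophage scavenger receptor gene MARCO was 5.44-fold lower. FBP1, SMIM25 and CCR1 were 4.43-fold, 3.87-fold and 3.66-fold lower, and DHX57 and VPS33A 4.12-fold and 3.76-fold lower. Of 12 macrophage genes 8 were lower, such as SPP1 (2.52-fold) and MRC1 (2.34-fold), and of 10 cytotoxic genes 9 were lower, such as PRF1 (2.59-fold), while IFNG was 1.67-fold higher. After centring on the median gene, 6 macrophage and 3 cytotoxic genes were lower. The cell shares of each library enter these sums. The median gene lay at a log2 ratio of -0.34 over all cells, -0.21 in T or NK-like and -0.26 in monocyte or macrophage-like cells, so counts of higher and lower genes shift when ratios are centred on it.

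Within the monocyte or macrophage-like class, inflammatory genes were far higher in the enzymatic library. All 14 genes of the NF-kB list, targets and regulators of an inflammatory transcription factor, were higher, with a median log2 ratio of 3.05, or 3.31 above the median gene. That median lay above all 10000 matched random lists (percentile 100). The immediate early, p53 and apoptosis, regulatory T (median 1.80) and matrix fibroblast (3.27) lists also reached percentile 100 in this class. The percentile alone therefore does not set the NF-kB list apart. CXCL8, which encodes a neutrophil-attracting chemokine (chromosome 4, 73740506 to 73743716), stood at 7431 CPM (7329 to 7534) in the enzymatic and 561 CPM (528 to 595) in the mechanical library, a 13.2-fold difference. IL1B, which encodes the cytokine interleukin-1 beta, was 7.59-fold higher (7.05 to 8.18), and TNF 18.9-fold higher (13.0 to 28.7). CXCL2 (15.3-fold), CXCL3 (13.1-fold), CCL20 (8.91-fold) and NFKBIA (3604 and 299 CPM) were higher too, and ICAM1 was 1.70-fold higher. CCL3 and CCL4 have near-identical copies, so their 5.45-fold and 3.85-fold differences are uncertain.

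By the ranking rule, SERPINB2, a protease inhibitor gene induced in activated monocytes, had 546 UMIs in the enzymatic and 0 in the mechanical class, at least 129-fold higher with the floor of 3 counts. IL1A, which lies on chromosome 2 (112773915 to 112784590) near IL1B (112829751 to 112836903), had 384 and 0 UMIs, at least 91.0-fold higher. DUSP2 (38.9-fold, 26.0 to 60.9), IL6 (25.8-fold), TCHH (21.6-fold) and HES1 (18.7-fold) were also higher, and LYPD3 had 79 against 1 UMIs, a ratio of 56.1 (9.79 to 2245). In the enzymatic library HES1 (134 against 251 CPM) and LYPD3 (28.8 against 32.7 CPM) stood no higher in this class than in all other cells, so this comparison does not exclude free RNA for them. COL1A1 and LUM stood at 10.6 and 11.7 CPM in this class, against 2514 and 1989 CPM over all enzymatic cells. Free RNA at the share of those fibroblast genes would not reach the levels of HES1 and LYPD3, whose own free share was not measured. PPARG, a transcription factor gene of lipid handling, was 4.92-fold lower (2.55 to 10.3). TMEM45A (4.48-fold), APOL2 (4.10-fold), AK4 (3.93-fold), ADO (3.78-fold), FN1 (3.70-fold), CPT2 (3.52-fold) and TEP1 (3.48-fold) were lower as well. These ranked genes, higher and lower, were not compared within single clusters, so the mix of clusters may enter their ratios. Cluster 13, led by MARCO and FBP1, held 8.82% of the enzymatic and 58.6% of the mechanical class. Cluster 4, led by SERPINB2, EREG and IL1B, held 35.9% and 1.15%.

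Of the 16 immediate early genes, which respond to stimuli within minutes, 14 were higher in the enzymatic monocyte or macrophage-like cells (median log2 ratio 1.56, 1.82 above the median gene). Examples were ATF3 (12.6-fold), IER3 (11.8-fold) and FOSB (4.60-fold), while EGR2 (35.3 and 35.4 CPM) and IER2 (180 and 140 CPM) were not called. Heat shock genes had a median of 0.46 (0.72 above the median gene), with 5 of 14 higher (9 after centring), such as DNAJB1 (3.87-fold) and BAG3 (2.78-fold), and HSPD1 (172 and 186 CPM) not called. With at most 10% mitochondrial UMIs this median was 0.28. Of 10 p53 and apoptosis genes 5 were higher, including PMAIP1 (7.82-fold) and GADD45B (4.22-fold). Of 10 unfolded protein response genes 3 were higher (5 after centring), with XBP1 at 2.29-fold. In the hypoxia list (median -0.57) BNIP3, PGK1 and P4HA1 were lower by 2.10-fold, 1.55-fold and 1.53-fold, and VEGFA was 1.93-fold higher, a direction that turned with at most 10% mitochondrial UMIs (log2 ratio -0.16). After centring, 2 hypoxia genes were higher and 1 was lower. The unnamed cluster with HILPDA and VEGFA among its leading genes (2 enzymatic and 20 mechanical cells) was left out of this class. Its best marker match was monocyte or macrophage (mean log2 ratio -0.609), and no cluster was unnamed under the 10% limit. In the monocyte list S100A8 (2.05-fold), VCAN (1.76-fold) and FCN1 (1.54-fold) were lower and THBS1 was 2.29-fold higher, and the median of -0.53 turned to 0.32 within cluster 12. After centring, 1 monocyte gene was higher and 1 was lower. Of 12 macrophage genes 11 were not called, C1QB for example with 2418 and 2100 CPM, and FOLR2 was 1.80-fold higher, while 3 were higher after centring. No MHC class II gene was called, but their median of 0.28 lay above the middle 95% of random lists (-0.30 to 0.21, percentile 98.5). By the fold of 1.5 alone, 5 of 10 were higher after centring. IFIT3 and OAS1 of 11 interferon genes were lower, though not with at most 10% mitochondrial UMIs (log2 ratios 0.066 and 0.079), and after centring 3 interferon genes were higher and 0 lower.

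After thinning to 1000 UMIs, 82.1% of enzymatic and 16.4% of mechanical monocyte or macrophage-like cells had a CXCL8 UMI (91.5% and 42.5% unthinned, median depths 8058 and 9727.5 UMIs). In T or NK-like cells, read as background, 1.81% and 4.24% had one (6.75% and 14.9% unthinned, median depths 3330 and 3750 UMIs). For IL1B the thinned shares were 52.8% and 13.5% in the monocyte or macrophage-like class, and 0.602% and 0.606% in T or NK-like cells. Different clusters held the class in each library. Cluster 4, led by SERPINB2, EREG and IL1B, had 110 enzymatic and 2 mechanical cells, cluster 13, led by MARCO and FBP1, had 27 and 102, and cluster 12, led by CCL18 and CCL13, had 169 and 70. Genes listed for other cell types were also higher in the enzymatic class. CXCL13, of the T exhaustion list, had 90.7 against 2.56 CPM. No gene of that list was called in T or NK-like cells, and the source of the CXCL13 UMIs was not tested. CD3D had 22.2 against 9.23 CPM and IGKC 59.0 against 17.9 CPM, and of 6 measured matrix fibroblast genes 4 were higher. The median of that list, 3.27, turned to -0.88 with at most 10% mitochondrial UMIs and to -1.05 with at least 50 UMIs per gene. The latter minimum left out all 4 higher genes, COL1A1 (29 and 1 UMIs), COL1A2 (36 and 2), COL3A1 (39 and 1) and LUM (32 and 0). FN1 (243 and 639 UMIs) stayed, so -1.05 reflects other members and no turn of these 4 genes.

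**Figure D2:**
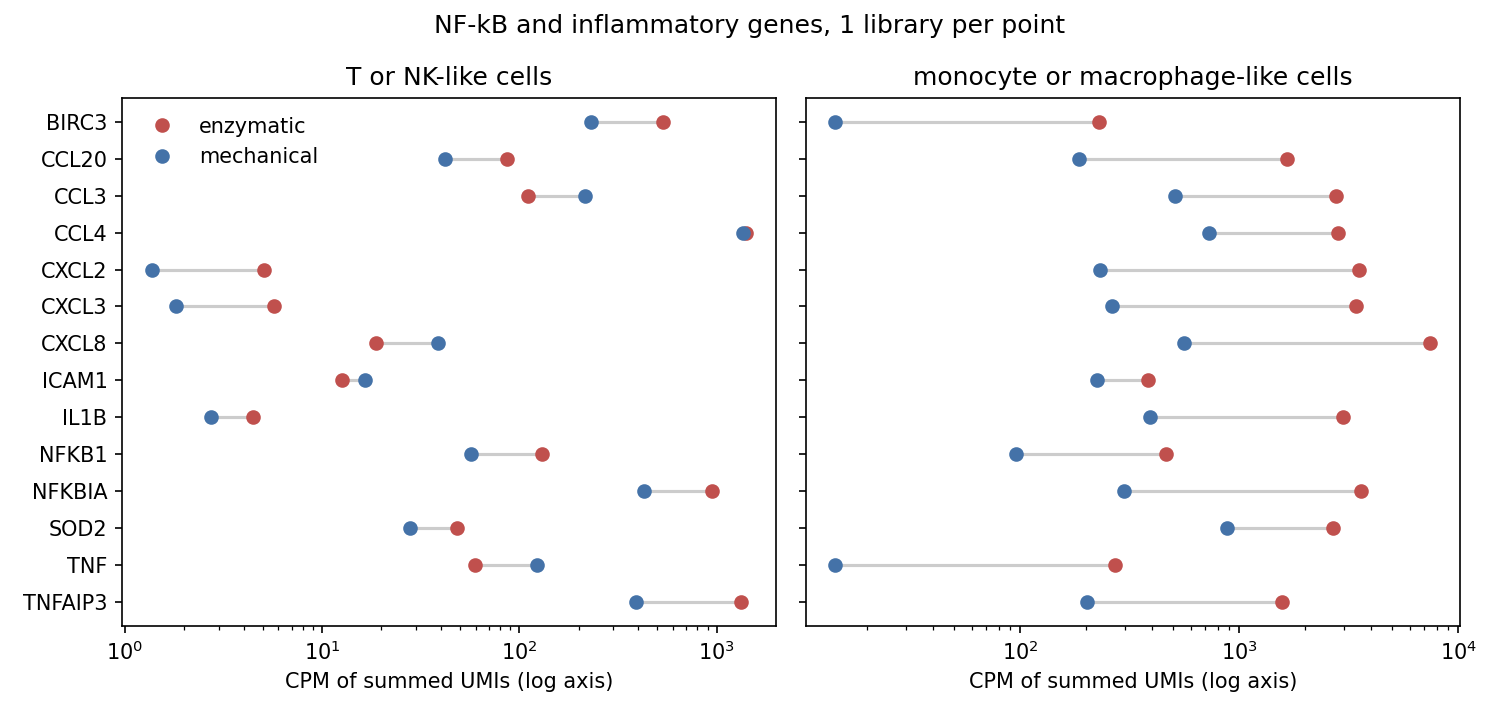
CPM of summed UMIs (log axis) of the NF-kB list genes in T or NK-like and monocyte or macrophage-like cells, with 1 point per library. In the monocyte or macrophage-like class all 14 genes lie higher in the enzymatic library, CXCL8 at 7431 against 561 CPM.

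Heat shock genes, which encode chaperones for unfolded proteins, were higher in the enzymatic T or NK-like cells. Of 14 measured genes 13 were higher, and HSPB1 (81.0 and 82.1 CPM) was not called. The list had a median log2 ratio of 1.52 (1.73 above the median gene, percentile 100 among random lists). The NF-kB and matrix fibroblast lists also reached percentile 100 in these cells. DNAJB1 stood at 475 CPM (452 to 499) in the enzymatic and 73.9 CPM (63.0 to 86.2) in the mechanical class, a 6.42-fold difference. HSPA6 was 14.7-fold higher (7.28 to 34.5), HSPH1 4.54-fold and DNAJA1 3.48-fold higher. Only 2.13% of enzymatic and 1.39% of mechanical cells had an HSPA6 UMI, so few cells carried that difference. HSPA1A and HSPA1B, neighbouring near-identical genes on chromosome 6 (31815464 to 31817946 and 31827735 to 31830255), were 5.24-fold and 6.50-fold higher, with the split between them uncertain. HSPA1A UMIs were in 30.8% of enzymatic and 26.7% of mechanical cells (17.2% and 8.28% thinned). For HSPA1B these shares were 25.6% and 10.8% (13.6% and 4.24% thinned). In the enzymatic library 9 of the 14 genes had no more CPM in T or NK-like cells than in all other cells, among them HSPA1A (734 against 1375 CPM), HSPA1B (382 against 714 CPM) and HSPA6 (53.5 against 105 CPM), so this comparison does not exclude free RNA for these. COL1A1 and LUM stood at 24.2 and 23.3 CPM in these cells, against 2514 and 1989 CPM over all enzymatic cells. Free RNA at the share of those fibroblast genes would not reach the levels of HSPA1A, HSPA1B and HSPA6. The share of free heat shock RNA itself was not measured. For DNAJA1, HSPA8, DNAJB1, HSPD1 and HSPE1 the ratio of this class to other cells lay between 1.04 and 1.90. This comparison was made after the data were seen. Cluster 9, led by IFNG, TNFSF9 and the heat shock genes HSPA1B and DNAJB1, held 37 enzymatic cells and 1 mechanical cell, and without it the median was 1.24.

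By the ranking rule, the elongation factor gene ELL2 was 9.56-fold higher (5.85 to 16.7) in the enzymatic T or NK-like cells, ZNF331 7.09-fold (5.69 to 8.92), TRAF4 5.84-fold, TNFSF9, a costimulatory ligand gene, 5.10-fold and RGCC 5.01-fold. ELL2 stood at 74.2 CPM there and at 132 CPM in all other enzymatic cells. CISH was 8.80-fold lower (5.22 to 15.7). DHX57 (3.65-fold), ZNF302 (3.61-fold), the proteasome gene PSMB10 (3.40-fold), SPOUT1 (3.22-fold), VPS33A (3.16-fold) and DENND2D (30.2 and 93.5 CPM) were lower too.

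Immediate early genes went both ways in these lymphocytes. ATF3 (9.17-fold), NR4A1 (2.75-fold), JUND (2.48-fold), KLF6 (1.79-fold) and ZFP36 (1.56-fold) were higher, while IER2 (1.83-fold), FOS (1.78-fold), SOCS3 (1.73-fold) and FOSB (1.63-fold) were lower, and 7 of 16 were not called (median 0.22, or 0.12 without cluster 9). After centring on the median gene, 7 were higher and 2 lower. The NF-kB list also split: TNFAIP3 (3.40-fold), BIRC3 (2.32-fold) and NFKBIA (2.22-fold) were among 6 higher genes, and TNF (2.07-fold), CXCL8 (2.06-fold) and CCL3 (1.92-fold) were lower (median 0.91), with CXCL8 at a level read as background in these cells, and after centring 9 were higher and 3 lower. Of 9 measured p53 and apoptosis genes 5 were higher, such as CDKN1A (3.59-fold) and PMAIP1 (3.41-fold). In the unfolded protein response list DDIT3 (3.87-fold) and ATF4 (2.13-fold) were among 4 higher genes, and PDIA4 and SDF2L1 were lower.

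Of 10 cytotoxic genes 7 were not called, granzyme gene GZMB with 991 and 1298 CPM among them, while PRF1 (1.72-fold) and GZMH (1.60-fold) were lower and IFNG was 2.52-fold higher. The cytotoxic median was -0.29, below the middle 95% of random lists (-0.21 to 0.30, percentile 0.26), and -0.08 relative to the median gene, with 1 gene higher and 0 lower after centring. No gene of the T exhaustion list was called (1 higher after centring), with PDCD1 at 152 and 131 CPM and CTLA4 at 317 and 375 CPM. In the regulatory T list TNFRSF4 (2.02-fold) and FOXP3 (1.62-fold) were lower and 6 of 8 were not called, while 2 were higher and 2 lower after centring. CCR7 (2.33-fold) and IL7R (1.51-fold) of 8 naive and central memory genes, and RGS1 (2.80-fold) of 6 tissue-resident genes, were higher. Of 12 proliferation genes UBE2C was lower and 11 were not called, but their median of 0.20 lay above the middle 95% of random lists (percentile 99.1), and after centring 4 were higher and 1 lower. That median turned to -0.0071 as a mean over cells and to -0.26 with at most 10% mitochondrial UMIs. Of 11 interferon genes 1 was higher and 2 were lower, against 3 and 1 after centring. Fibroblast transcripts were present here as well: COL1A1 had 81 UMIs in the enzymatic and 0 in the mechanical T or NK-like cells, and the matrix fibroblast median of 4.60 is 3.13 with genes at 0 set to their bound. The macrophage genes SPP1 (4.99-fold) and LYZ (5.16-fold) were lower in the enzymatic T or NK-like cells.

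**Figure D3:**
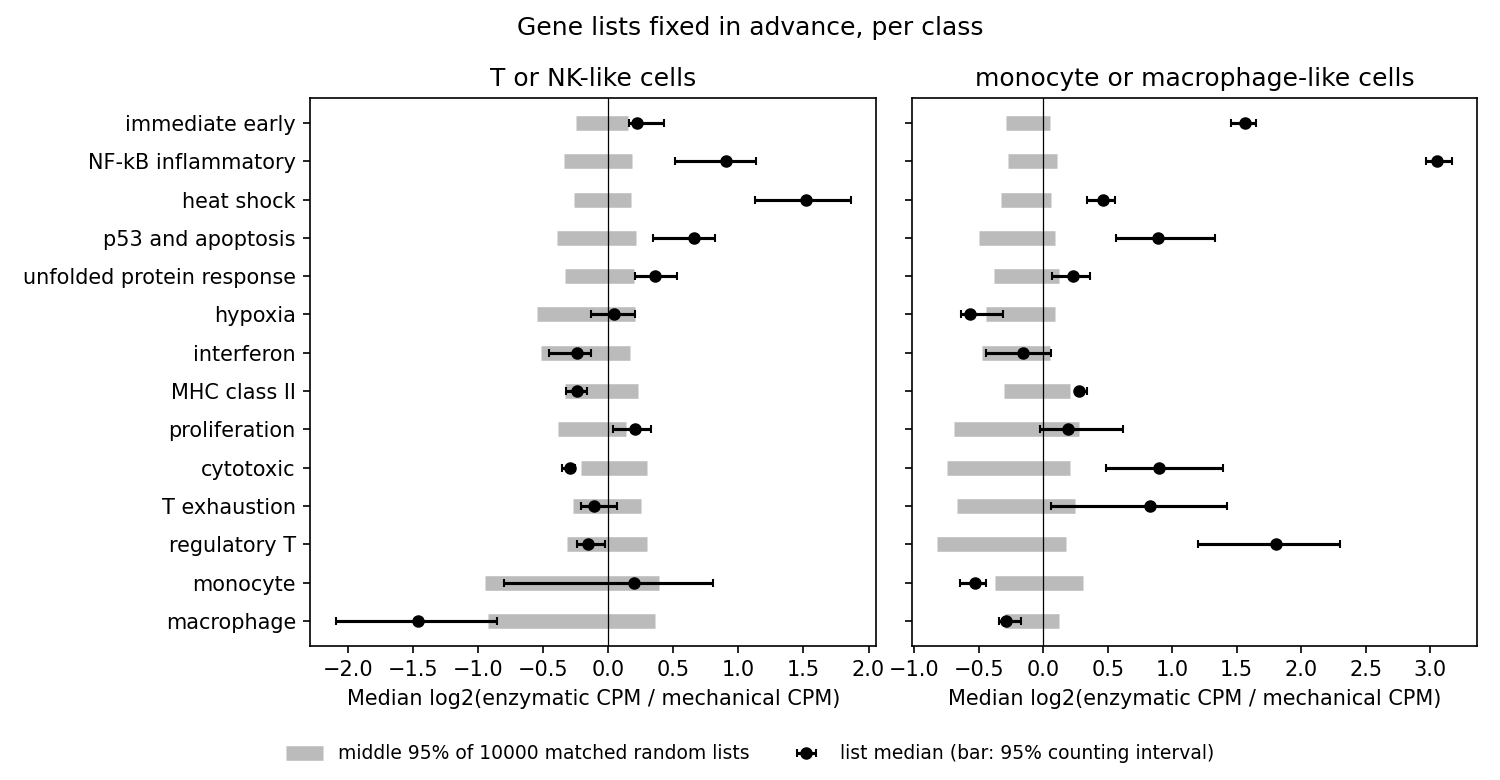
Median log2 ratio of enzymatic to mechanical CPM per gene list in T or NK-like and monocyte or macrophage-like cells (points, with 95% counting intervals) over the middle 95% of 10000 matched random lists (grey). The NF-kB list stands at 3.05 in the monocyte or macrophage-like class and the heat shock list at 1.52 in the T or NK-like class.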

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

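The measurements here were chosen after the result was seen. Among barcodes clustered without the cell filter, a cluster led by mitochondrial transcripts held 9.95% (8.84 to 11.2) of the enzymatic and 14.2% (12.3 to 16.1) of the mechanical barcodes, a signal in barcodes that the comparisons do not use. The median mitochondrial share in this cluster was 95.3% in the enzymatic and 96.8% in the mechanical library. Endothelial-like cells, which line vessels, lay mostly outside the filter: 73.1% (52.2 to 88.4) of 26 enzymatic and 73.3% (60.3 to 83.9) of 60 mechanical endothelial-like barcodes were removed, against 24.8% and 26.0% of T or NK-like barcodes. The filter also removed 44.1% (33.8 to 54.8) of enzymatic and 26.3% (9.15 to 51.2) of mechanical mast-like barcodes, 37.5% (32.2 to 43.1) and 28.6% (3.67 to 71.0) of fibroblast-like barcodes, and 18.1% (11.3 to 26.8) and 39.6% (25.8 to 54.7) of B-like barcodes. Of barcodes in unnamed clusters, which include the mitochondrial one, 74.2% and 99.5% were removed.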

How the results depend on the processing

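The alternatives were chosen before the data were examined, except the shared macrophage cluster, the class without cluster 9, the class with dendritic-like cells joined and unnamed clusters counted under their best match, which were chosen after the result was seen. With each cell scored on its own the pericyte difference was 0.661 (-0.538 to 1.68) and the neutrophil ratio of mechanical to enzymatic share 3.40, against 14.9. The fibroblast-like share stayed higher and the neutrophil-like share lower in the enzymatic library under every alternative that gave a value. Among alternative values for shares of cells, 81 stayed within the counting interval, 25 moved and 2 reversed, and among those for the 6 leading list medians 38 stayed and 13 moved. Among other list medians 351 stayed, 121 moved and 9 reversed, and among single genes 1099, 453 and 4. Differences in share are enzymatic minus mechanical, in percentage points. With at most 10% mitochondrial UMIs (751 and 350 cells, median mitochondrial share 7.08% and 7.70%, mechanical median 4625.5 UMIs) they were 12.7 for epithelial, 12.6 for fibroblast, 6.81 for plasma, -0.269 for mast (from 1.27, an interval that includes 0), -9.33 for neutrophil, -11.8 for monocyte or macrophage, -11.0 with dendritic cells joined and -25.3 for all leukocytes. With no cell filter (2643 and 1342 barcodes, medians 3419 and 3196.5 UMIs, 13.8% and 15.1% mitochondrial) they were 4.14 for epithelial, -3.49 for endothelial, -7.88 for T or NK and for monocyte or macrophage, and -7.66 with dendritic cells joined. An unnamed cluster of 132 enzymatic cells and 1 mechanical cell matched monocyte or macrophage best there, and counted in that class it left -2.96, -2.74 with dendritic cells joined and -8.60 for leukocytes. Leiden resolution 2 gave 1.98 for dendritic, -9.82 for monocyte or macrophage, -7.84 for both and -18.8 for leukocytes. Unnamed clusters of leukocyte best match with a score above 0 held 147 enzymatic and 30 mechanical cells there, and counted under that match they left -5.39, -3.41 and -14.0 for the last 3 values. With each library clustered on its own the values were 9.99 for monocyte or macrophage and -0.193 for plasma, both reversed, 5.996 for monocyte, macrophage or dendritic (from -3.41) and -3.99 for dendritic (from 0.227), which turned as well from values whose intervals include 0, 4.89 for B, 4.25 for epithelial and -2.97 for leukocytes. With the 94 mechanical cells of an unnamed cluster counted under their best match, monocyte or macrophage, the class stood at -1.38 (-4.69 to 1.80), -5.37 with dendritic cells joined, and leukocytes at -14.3, so 9.99, 5.996 and -2.97 rest on that cluster having no name. Clustering without stress, mitochondrial and ribosomal genes gave 4.44 for dendritic, -10.2 for monocyte or macrophage and -5.77 for both, with 156 enzymatic and 43 mechanical cells of a cluster led by CD1A, CD1C and EREG, with IL1B, named dendritic. In the monocyte or macrophage class the NF-kB median was 3.31 centred on the median gene, 3.22 as a mean over cells, 2.48 with at most 10% mitochondrial UMIs, 2.64 with doublets kept, 2.60 in the shared cluster and 2.76 with dendritic cells joined. The immediate early median was 1.82 centred and 1.39 with at most 10% mitochondrial UMIs, and the heat shock median 0.72 and 0.28. In T or NK cells the immediate early median was 0.43 centred, 0.45 as a mean over cells and 0.12 without cluster 9. Reversed values of other lists were proliferation in T or NK cells (-0.0071 as a mean over cells, -0.26 with at most 10% mitochondrial UMIs), squamous differentiation there (-0.37 with at least 50 UMIs), T exhaustion (-0.28 with at least 50 UMIs), monocyte (0.32 in the shared cluster) and matrix fibroblast genes (-0.88 with at most 10% mitochondrial UMIs, -1.05 with at least 50 UMIs) in monocyte or macrophage cells, and hypoxia over all cells (-0.035 as a mean over cells, -0.56 with at most 10% mitochondrial UMIs). In monocyte or macrophage cells the log2 ratios of IFIT3 (0.066), OAS1 (0.079), MMP1 (-0.65) and VEGFA (-0.16) reversed with at most 10% mitochondrial UMIs, and so did the difference in cells with an HSP90AA1 UMI when not thinned (-2.01 points). The 4 matrix fibroblast genes higher in monocyte or macrophage cells had fewer than 50 UMIs each, so -1.05 rests on other members. On its own, the mechanical library held 0 B-like and 35 plasma-like cells, against 28 and 7 jointly. The B and plasma values therefore rest on naming. That library also held 26 epithelial-like cells and no endothelial-like class on its own, against 10 and 16 cells jointly. The epithelial value may thus rest on naming too. With doublets kept, the mechanical monocyte or macrophage class held 195 cells, against 174, and no cluster was unnamed. Apart from these effects of naming, unnamed clusters and list members, the cause was not tested for any of these. B, endothelial and pericyte classes gave no value with at most 10% mitochondrial UMIs, nor did dendritic cells at resolution 0.5 or endothelial cells with each library on its own. Classes with few mechanical cells, such as 5 fibroblast-like cells, allow no comparison of genes at this depth.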

Other observations

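B-like, mast-like and dendritic-like cells were too few in the mechanical library (28, 14 and 16 cells) for the main gene comparison, and their lists were chosen after the data were seen. Immediate early genes were higher in the enzymatic library in all of these classes: 9 of 13 measured genes in B-like cells (median log2 ratio 1.12), 12 of 13 in mast-like cells (1.81) and 13 of 16 in dendritic-like cells (1.46). NF-kB genes had medians of 0.96 (2 of 6 higher), 2.38 (6 of 7) and 2.75 (12 of 14) in the same order. Heat shock genes had medians of 0.33 in B-like, 1.65 in mast-like and 0.07 in dendritic-like cells, with 2 of 10, 6 of 11 and 4 of 11 higher, and 1 lower in mast-like cells. The B-like and dendritic-like medians lay within the middle 95% of matched random lists (-0.34 to 0.38 and -0.52 to 0.29).

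Epithelial-like cells fell on both sides of a limit of 2% mitochondrial UMIs, which was set after the data were seen. Below it lay 96 of 131 enzymatic and 5 of 10 mechanical cells (5.46% and 0.605% of kept cells), with medians of 1667.5 and 1497 UMIs. In both libraries the median MALAT1 level of these cells, a transcript retained in the nucleus, was 0 per 10000 UMIs. The cells at or above the limit, 35 enzymatic and 5 mechanical, had medians of 22648 and 12661 UMIs and MALAT1 levels of 134 and 266 per 10000 UMIs. T or NK-like cells of both libraries had a MALAT1 median of 568 per 10000 UMIs.

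Of the tests that follow, those of the macrophage cluster mix and of neutrophil depth had their outcomes set out beforehand, though the value within the shared cluster was added after the data were seen, and all others were chosen after the result was seen. The NF-kB genes of the monocyte or macrophage class were higher in the enzymatic library. Free RNA from other cells would leave these genes at or below the level of those cells, but the class held a median of 6.24 times their CPM in the enzymatic library, with 13 of 14 genes above 1 and BIRC3 at 0.752. A different mix of macrophage clusters alone would leave no difference within a cluster, but in the cluster shared by both libraries, itself built with these genes among the variables, the median log2 ratio was 2.60 (2.48 to 2.73). The enzyme step and the tissue fraction cannot be told apart with 1 library per step, so the enzymes, the time in suspension or different cells in the residue may each contribute.

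The fibroblast-like share was higher in the enzymatic library. A loss of mechanical fibroblasts to the mitochondrial filter would close the gap without a filter, but the difference was then 11.5 points (10.1 to 12.8). This covers only barcodes that could still be named. Without the filter, 9.95% of enzymatic and 14.2% of mechanical barcodes lay in a cluster led by mitochondrial transcripts, where fibroblasts could not be recognised. Cluster naming would close the gap when each cell was scored on its own, but the difference was 10.7 points (9.06 to 12.3). A hypothesis left open is that fibroblasts may stay in the solid residue until the matrix is cut, which these libraries do not test.

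The neutrophil-like share was higher in the mechanical library. Lower depth of the enzymatic library could push these low-RNA cells below the lowest UMI count called as a cell. Mechanical neutrophil-like cells were thinned by the depth factor of 0.678 taken from mast-like cells. Those left with at least 500 UMIs were 2.04% of mechanical cells, with a lower limit of 1.11%, above the upper limit of 0.662% in the enzymatic library. The rule for cells left counted UMIs alone, without the limit of 200 genes or the naming step. With each cell scored on its own in both libraries, the enzymatic share rose to 1.42%. The same thinning then left 3.29% (27.2 cells), with a lower limit of 2.16%, little above the enzymatic upper limit of 2.09%. For 26 of 827 cells the lower limit would be 2.06%, below that upper limit. Under this scoring the margin is therefore too small to set lower depth aside. This second check was made after the result was seen. Early release from the tissue or loss during the enzyme step were not tested, and no biological explanation was tested.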
